A study of Mus musculus and Homo sapiens
Mus musculus with 16 samples.

How the data were processed

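The samples were H3K4me3 PLAC-seq libraries of mouse fetal forebrain, 2 at the embryonic stage E12.5 and 2 at E16.5. Per the labels' protocols, frozen tissue was crosslinked with formaldehyde, digested with MboI, filled in with biotinylated nucleotides, ligated and sonicated, and an H3K4me3 antibody enriched the ligation products. Per the submitters' processing notes, BWA and SAMtools were used and the genome build was mm10; versions, the interaction caller and its thresholds are not given in the sources used here. Per the file headers, each deposited file lists called interactions between bins of 10 kb, called in each library separately. The files hold intrachromosomal pairs on 19 autosomes, 20 to 1000 kb apart, each with an observed count at least 2 times its expected count and an FDR under 0.01.

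Per the file headers, the authors give for each interaction the count of read pairs, an expected count from their model, an FDR (a q-value), a cluster label, size and type, the −log10 p of the cluster, and a mark of the cluster's summit. What the expected count corrects for is not stated. The counts were used as deposited. The total count in listed interactions was 405491 to 911710 read pairs per library, with a median of 19 to 20 per interaction. Library depth is unknown, so a bin pair that is not listed is not known to be uncontacted. A count of 0 listed interactions means that none passed the authors' threshold.

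Genes came from a RefSeq table of GRCm38.p6, the assembly of the same primary sequence as mm10, with 20665 autosomal protein-coding genes. The table gives no strand, so gene starts could not be placed. A promoter bin was therefore replaced by a gene-end bin, which holds either end of at least 1 such gene; 30812 bins qualified. Genes that share a bin cannot be told apart. For the gene lists, each gene was given its end bin with the higher sum over the 4 libraries. This choice does not use the stage labels, but the longer E16.5 lists weigh more in it. Coordinates are 1-based.

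Contact strength was tested on the read-pair counts of 6875 bin pairs listed in all 4 libraries, and contact number on the number of listed interactions that touch a bin, for 2449 gene-end bins and for 4758 bins of any kind with a sum of at least 10 over the libraries. Both used edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust quasi-likelihood dispersion, stage as the sole term and Benjamini-Hochberg adjustment at 0.05; changes are E16.5 minus E12.5. The SE is the log2 change divided by the root of the quasi-likelihood F. Contact strength covers only contacts past the authors' threshold in every library, and leaves out those gained or lost. There were 17 gene lists with 421 symbols, of which 408 lay on autosomes, 12 on other chromosomes and 1 was not matched; 184 had a tested bin. The 13 lists with at least 3 tested bins were tested with camera of limma 3.58.1 (two-sided, preset correlation 0.01), with camera's estimated correlation and fry beside it. List medians with bounds place a bin at 0 in both libraries of a stage at the change that 3 listed interactions over that stage would give. Numbers of interactions, overlap, distance and classes were compared with exact tests over the 6 assignments or 3 pairings of the libraries.

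Named genes followed a rule. For each direction, the 10 gene-end bins with the smallest p past the threshold that hold 1 or 2 genes and moved the same way in every E16.5 library against every E12.5 library (after scaling) were named. For each list, the 3 members with the smallest p and any member past the threshold, up to 6, were named. For contacts, the 10 with the smallest p per direction that touch such a bin and moved the same way in every library were taken, at most 1 per gene-end bin, and for restricted interactions the 5 bins with the most per stage. The text leaves out 1 contact and 1 list member that the rule picked. The tests, lists, rule and most alternatives were fixed before the data were examined; the use of gene ends, the whole gene span, the better-connected end, the contact strength of lists and the quasi-dispersion of at least 1 were chosen afterwards. The alternatives were the library total without TMM, DESeq2 1.42.0, the authors' expected count as an offset, normalization within 10 distance bins, stricter and looser filters, lists cut to the 16075 interactions with the lowest FDR, an FDR under 0.0001, clusters counted once, read pairs in place of interactions, distances of at most 200 kb, the replicate number as a block and each library left out.

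Replicates were checked for duplication. Over shared contacts with a mean of at least 40 read pairs, the chi-square of the counts was 1.30 times its degrees of freedom for the E12.5 pair (1555 contacts) and 1.75 times for the E16.5 pair (3376 contacts), so each pair differed by more than counting noise. Over all contacts shared by a pair the ratio was 0.846 and 0.935. The median quasi-dispersion of contact number was 0.635, below the value of 1 of Poisson counts; the cause of these low values was not tested.

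The tests were run first on simulated counts with the real means and 200 changed items. Over 6875 simulated contacts, 14.9%, 44.8% and 95.5% of changes of 1.5, 2 and 3 fold were recovered and 5.5% of calls were false. Over 2449 simulated gene-end bins, 4.5%, 37.3% and 75.8% of changes of 2, 4 and 8 fold were recovered with 6.02% false calls, so smaller changes in number are mostly not detected; these folds replaced 1.5, 2 and 3, of which few were recovered. Over 4758 simulated bins of any kind, 3%, 19.4% and 60.6% of the same changes were recovered with 6.78% false calls. The preset-correlation list test gave p under 0.05 for 0.5% of 200 random lists of unchanged bins. The simulation draws independent bins and no authors' threshold. It also draws the gene-end bins at close to Poisson spread, while the fit to the real numbers had a median quasi-dispersion of 0.635. The shares of recovered and false calls therefore need not carry over to the real gene-end bins. Python with pandas, numpy and scipy did the remaining steps.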

Results

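H3K4me3 PLAC-seq was analysed in mouse fetal forebrain at the embryonic stages E12.5 and E16.5, with 2 libraries per stage. PLAC-seq joins DNA ends that lie close together in the nucleus by ligation and then enriches, with an antibody, the ligation products that carry a histone mark. H3K4me3 is a mark of active and poised promoters, so the listed interactions are mostly those of promoters with other parts of the same chromosome. Each file lists the pairs of 10 kb bins (mm10) that the authors called as interacting, with the read pairs that support each. The series holds 16 samples; the other 12, which are single-cell libraries of a cell mix, adult cerebral cortex and fetal forebrain, were not analysed here. The E12.5 libraries listed 18413 interactions in replicate 1 and 16075 in replicate 2, supported by 446855 and 405491 read pairs. The E16.5 libraries listed 35291 and 36794 interactions, supported by 892987 and 911710 read pairs. The total sequencing depth is unknown, since the files hold only called interactions. Nothing in the labels says that replicates came from separate litters, so p-values measure only the spread between these samples.

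The E16.5 libraries listed 2.09 times as many interactions as the E12.5 libraries. The mean number was 36042.5 ± 1062.8 (SD, n = 2) at E16.5 and 17244 ± 1653.2 (SD, n = 2) at E12.5. The difference was larger than the spread between replicates, but 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333, and this was the value reached. By the Jaccard index, the share of the bin pairs of 2 lists that both hold, overlap was higher within a stage than between stages. The Jaccard index was 0.379 for the E12.5 pair and 0.405 for the E16.5 pair, against 0.259 to 0.282 for the 4 pairs of libraries from different stages. The exact p over the 3 ways to pair the libraries was 0.333, the smallest possible. The unequal lengths of the lists lower the index between stages. As a percent of the shorter list, shared bin pairs were 58.9% in both within-stage pairs and 61.85% to 67.63% between stages. With lists of equal length the index stayed higher within a stage. Of 58543 bin pairs listed in any library, 6875 were listed in all 4.

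Between E12.5 and E16.5, the bins of Arpp21, Prdm8, Myt1l, Cnr1 and Gria2 gained listed interactions, while those of Tbx3, Emx2 and Pax2 had fewer. A bin was linked to a gene when it held either end of a protein-coding gene, because the gene table gives no strand. The text calls it a gene-end bin, and it need not hold the promoter. The comparison asks which gene-end bins changed the number of 10 kb bins listed as their partners. Neighbouring partner bins count separately. All changes in number are relative to the library's total over gene-end bins. The strongest gains included Arpp21, a cAMP-regulated phosphoprotein gene, with 0 and 0 listed interactions at E12.5 and 37 and 44 at E16.5. Prdm8, a transcriptional regulator gene, went from 3 and 0 to 55 and 55, a 20.7-fold relative increase (log2 change 4.37, SE 0.49, adjusted p = 0.00868 by edgeR's quasi-likelihood test). Myt1l, a neuronal zinc finger gene, had 1 and 1 listed interactions at E12.5 and 28 and 46 at E16.5 (adjusted p = 0.00925). The cannabinoid receptor gene Cnr1 had 3 and 0 against 41 and 46 (adjusted p = 0.00925).

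Receptor genes were also among the gains. Gria2, an AMPA receptor subunit gene, rose 6.49-fold in relative number, from 3 and 3 to 29 and 38 (log2 change 2.70, SE 0.37, adjusted p = 0.00925). Grin2b, an NMDA receptor subunit gene, had no listed interaction in either E12.5 library and 15 and 20 at E16.5 (adjusted p = 0.00931). The other named gains were the sialyltransferase gene St3gal1 (3 and 2 against 29 and 37), the kinase gene Tnik (0 and 2 against 31 and 40), the nuclear receptor gene Nr4a3 (6 and 3 against 37 and 47) and the polo-like kinase gene Plk2 (9 and 8 against 45 and 58). Their adjusted p-values were 0.00925, 0.00925, 0.00931 and 0.00931.

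In the other direction, the bin at Emx2 on chromosome 19 (59460001 to 59470000), a homeobox gene of cortical patterning, fell from 48 and 51 listed interactions to 29 and 33. This was a 2.67-fold relative decrease (log2 change -1.42, SE 0.17, adjusted p = 0.00925). The T-box gene Tbx3 had 13 and 11 listed interactions at E12.5 and 0 and 0 at E16.5 (adjusted p = 0.00868). Pax2, a gene of the midbrain-hindbrain boundary, had 8 and 8 against 0 and 1 (adjusted p = 0.0127). For Lhx2, a LIM-homeobox gene of the cortex, the bin at its higher-coordinate end (chromosome 2, 38360001 to 38370000) fell from 14 and 16 to 0 and 2 (adjusted p = 0.00925). The bin at the lower-coordinate end of Lhx2 had 15 and 17 against 20 and 24 and did not pass (adjusted p = 0.666). The radial glia list used this lower-coordinate bin. The remaining named bins were those of Cd40 (14 and 18 against 4 and 5), Zfp36l1 with the predicted gene Gm52006 (43 and 39 against 31 and 37), Dmrta2 (12 and 11 against 5 and 5), Irx3 (21 and 16 against 10 and 6) and Hoxb4 (15 and 11 against 5 and 1). Their adjusted p-values ran from 0.00931 to 0.0154. The tenth, Mn1, had almost equal numbers, 69 and 69 against 70 and 68, and was lower only relative to the longer E16.5 lists (adjusted p = 0.0146).

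**Figure D1:**
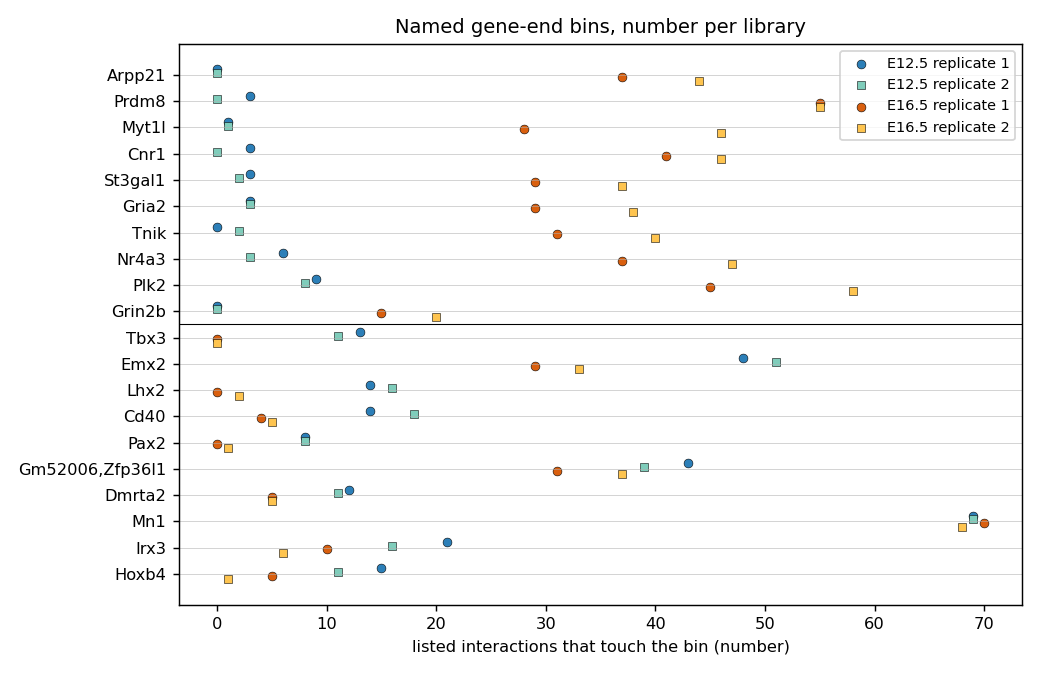
The plot of listed interactions per named gene-end bin gives the number in each of the 4 libraries (x axis) for 10 bins that were higher at E16.5 (above the line) and 10 that were lower relative to the library total (below the line). Arpp21 sits at 0 in both E12.5 libraries and at 37 and 44 in the E16.5 libraries, and Mn1 is near 69 in all 4.

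In all, 234 of 2449 tested gene-end bins passed an adjusted p of 0.05, 181 higher and 53 lower at E16.5. Of the 53 lower bins, 45 also had lower raw numbers in both E16.5 libraries and 8 did not. Of the 181 higher bins, 96 had 0 listed interactions in both of the shorter E12.5 lists. Of the 53 lower bins, 4 had 0 in both E16.5 lists. The split between directions moved with the scaling: 77.4% of the calls were higher with TMM and 63.9% with the library total alone, and the median bin changed by 0.19 on the log2 scale with TMM and by 0.01 without. The count depends on how the spread between 2 replicates is estimated. Without E16.5 replicate 1 or without E16.5 replicate 2 no bin passed (451 and 349 had an unadjusted p under 0.05), while 120 and 143 passed without E12.5 replicate 1 and without E12.5 replicate 2. Counting each cluster of neighbouring interactions once also left 0 bins by edgeR (89 of 887 with an unadjusted p under 0.05). With the quasi-dispersion held at 1 or above, a setting chosen after seeing the data, 20 bins were higher and 4 lower, and DESeq2 called 32 and 8. Over all 4758 bins with or without a gene end, edgeR called 0 (939 with an unadjusted p under 0.05) and DESeq2 called 60 higher and 12 lower. This 0 also depends on the setting: edgeR called 404 higher and 95 lower without E16.5 replicate 1, 223 and 41 without E16.5 replicate 2, 229 and 103 with a sum of at least 20, and 466 and 119 with the replicate number as a block.

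Synaptic and neuronal excitability genes as a list had more listed interactions at E16.5. Of 14 tested bins, 6 rose and 8 did not pass; 9 rose when adjusted over the list alone. The 6 were those of Gria2, Grin2b, the synaptotagmin gene Syt4 (0 and 0 against 10 and 11), the potassium channel gene Kcnq3 (0 and 0 against 13 and 10), the neuroligin gene Nlgn1 (0 and 0 against 6 and 7) and the AMPA receptor subunit gene Gria1 (0 and 0 against 8 and 5). Raw numbers were higher in both E16.5 libraries than in both E12.5 libraries for 14 of the 14 bins. With the longer E16.5 lists, this also held for 1445 of all 2449 tested bins, and 102 were lower in both. At E12.5, 8 of the 14 bins had no listed interaction in either library. With these at their bound, the median log2 change was 1.37. Bins needed a sum of at least 10 over the libraries, so these 8 were tested only through their E16.5 numbers. The list's adjusted p was 3.09e-05 with camera's preset correlation and 0.274 with an estimated correlation.

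Genes of neurite growth, the cytoskeleton and axon guidance were also higher as a list, with 6 of 23 tested bins past the threshold, 17 not, and 7 higher and 1 lower when adjusted over the list alone. Ncam1, a neural cell adhesion molecule gene, rose from 7 and 3 to 36 and 50 (5.06-fold, adjusted p = 0.0121). Tenm2, a teneurin gene, had 0 and 0 against 12 and 19, and the ephrin receptor gene Epha5, which shares its bin with the predicted gene Gm42163, had 0 and 0 against 7 and 10. The semaphorin receptor genes Nrp1 (20 and 15 against 56 and 60), Plxna4 (14 and 10 against 39 and 57) and Plxna2 (2 and 3 against 29 and 16) rose as well. The list's adjusted p was 0.0175, and 0.300 with an estimated correlation. With lists of equal length it did not pass (adjusted p = 0.227), and its median log2 change went from 0.69 to 0.25.

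Deep-layer projection neuron genes were higher as a list, with 5 of 12 tested bins past the threshold over all bins and over the list alone, and 7 not past it. The bin of Tbr1, which it shares with Psmd14, rose from 3 and 3 to 27 and 20 (4.56-fold, adjusted p = 0.0205). Zfpm2 had 0 and 0 against 11 and 10, Rprm 4 and 3 against 22 and 21, Tshz3 with Gm36722 19 and 27 against 65 and 77, and Sox5 0 and 0 against 6 and 5. The list's adjusted p was 0.0234, and 0.300 with an estimated correlation. It was 0.126 without E16.5 replicate 1 and 0.132 with lists of equal length.

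The list of non-forebrain patterning genes had fewer listed interactions at E16.5 relative to the library total in 27 of 27 tested bins, of which 8 passed the threshold and 19 did not; the counts were the same when adjusted over the list alone. These genes mark the hindbrain, the midbrain or other regions outside the telencephalon. Most of the 27 bins lie close to one another in the Hox clusters, so they are not independent (estimated correlation 0.604). Besides Pax2 and Hoxb4, the bins of Pax7 (9 and 4 against 0 and 0), Hoxa10 with Hoxa11 (8 and 4 against 0 and 0), Hoxb3 with Hoxb5 and Hoxb6 (21 and 16 against 12 and 5) and Pax3 (8 and 3 against 1 and 0) fell. Their adjusted p-values were 0.0195, 0.0197, 0.0254 and 0.0404. Raw numbers were lower in both E16.5 libraries for 8 of the 27 bins and higher for 2. The list's median log2 change was -0.93, with an adjusted p of 4.84e-09, and 0.365 with an estimated correlation.

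Diencephalic and choroid plexus genes were lower as a list. Of 15 tested bins, 4 fell, 11 did not pass, and 7 fell when adjusted over the list alone. Irx3, a homeobox gene, the Wnt pathway transcription factor genes Lef1 (17 and 25 against 9 and 14) and Tcf7l2 (14 and 18 against 12 and 8) and the homeobox gene Barhl2 (16 and 14 against 11 and 9) were the 4. The list's median log2 change was -1.02 and its adjusted p was 1.41e-06, and 0.300 with an estimated correlation.

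Radial glia and neural progenitor genes were lower as a list. Of 21 tested bins, 4 fell, 17 did not pass, and 11 fell and 1 rose when adjusted over the list alone. After Emx2, the Notch effector gene Hes1 fell from 31 and 33 to 26 and 25 (2.10-fold relative to the library total, adjusted p = 0.0179). Otx2 had 9 and 4 against 1 and 0 (adjusted p = 0.0256). Sox2, a gene of neural stem cells, had 31 and 34 against 33 and 26 and was lower only relative to the library total (1.84-fold, adjusted p = 0.0421). Raw numbers were lower in both E16.5 libraries for 6 of the 21 bins and higher for 8. The list's median log2 change was -0.72 and its adjusted p was 8.76e-06, and 0.274 with an estimated correlation.

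The list of early developmental timing genes was lower (2 of 7 bins fell, Dmrta2 and Hmga2, and 5 did not pass; adjusted p = 0.0193, and 0.300 with an estimated correlation). Dmrta2, at its second end bin, had 12 and 13 against 7 and 4, and the chromatin protein gene Hmga2 had 22 and 13 against 10 and 10; Fzd5 had 4 and 7 against 3 and 6 (adjusted p = 0.343). The GABAergic and ganglionic eminence list was lower (2 of 23 bins fell and 21 did not pass; adjusted p = 0.0181, and 0.464 with an estimated correlation). Its 2 bins were those of Sp8 (22 and 18 against 16 and 12) and Dlx2 (19 and 17 against 16 and 12); Six3 had 32 and 34 against 36 and 26 (adjusted p = 0.0573). Of 5 cell cycle bins, that of Ccnd1, shared with LTO1, fell from 14 and 15 to 9 and 8, and 4 did not pass (list adjusted p = 0.0234, and 0.300 with an estimated correlation). Ccnd2 had 16 and 21 against 14 and 23, and Rrm2 had 3 and 4 against 4 and 3. Of 4 bins of meninges and mesenchyme genes none passed, with the smallest p-values at Foxd1, Msx1 and Foxc1, and the list was lower (adjusted p = 0.0175, and 0.405 with an estimated correlation). With lists of equal length none of these 4 lists passed (adjusted p from 0.107 to 0.227). The call of the GABAergic list ended without E16.5 replicate 2 (adjusted p = 0.186), that of the early timing list without E16.5 replicate 2 (adjusted p = 0.0537) and that of the cell cycle list without E12.5 replicate 2 (adjusted p = 0.0788). When adjusted over the list alone, 2 early timing bins, 5 GABAergic bins and 1 cell cycle bin fell, and 1 GABAergic bin rose. These lists were lower relative to the library total. Raw numbers were higher in both E16.5 libraries for 10 of the 23 GABAergic bins and lower for 2. They were higher for 3 and lower for 2 early timing bins, and higher for 1 and lower for 1 in both the cell cycle and meninges lists.

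Upper-layer projection neuron genes, intermediate progenitor genes and glial genes did not pass as lists, with adjusted p of 0.361, 0.361 and 0.0547. Of 12 upper-layer bins, 3 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. Lmo4 rose from 6 and 9 to 34 and 38, Bhlhe22 from 3 and 1 to 32 and 18, and Dok5 from 0 and 0 to 7 and 6. The POU-domain genes Pou3f3 (42 and 39 against 38 and 40) and Pou3f2 (20 and 23 against 16 and 19) were lower relative to the library total. Of 12 intermediate progenitor and neurogenic bins, 2 rose, 1 fell and 9 did not pass, and 2 rose and 1 fell when adjusted over the list alone. The 2 that rose were those of the neuronal transcription factor genes Neurod6 (0 and 0 against 21 and 15) and Neurod1 (0 and 0 against 9 and 15). This list's median log2 change was -0.38 while its mean was 0.81, and its test pointed down. Of 8 glial bins, Olig2 fell from 8 and 7 to 2 and 0, also over the list alone, and 7 did not pass; Zbtb20 had 1 and 0 against 6 and 5 and Pdgfra 19 and 21 against 24 and 24. Microglia and housekeeping genes had 1 tested bin each, those of Cd68 (3 and 6 against 4 and 0, adjusted p = 0.264) and Actb (2 and 1 against 11 and 2, adjusted p = 0.477). Endothelial and erythroid genes had 0 tested bins.

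**Figure D2:**
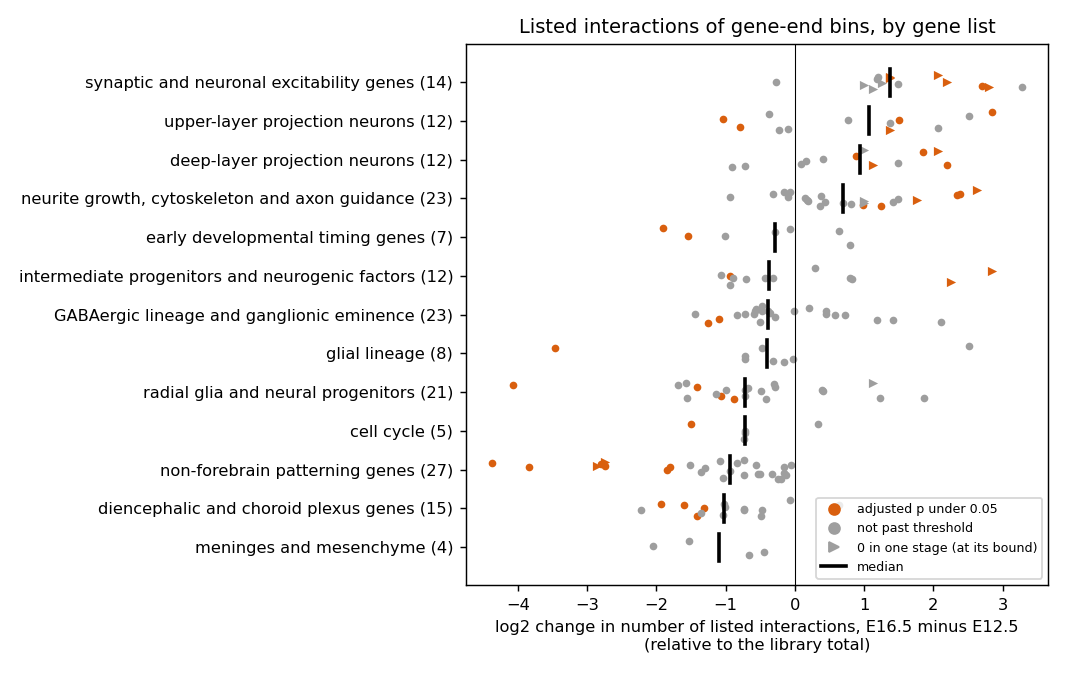
The plot of log2 change by gene list shows each tested gene-end bin as a point (E16.5 minus E12.5, relative to the library total) and the list's median as a bar; triangles are bins at 0 in both libraries of a stage, placed at their bound. The medians run from -1.10 for the meninges list to 1.37 for the synaptic list.

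Among contacts listed in all 4 libraries, contacts of Neurod2, Zbtb18 and Nfib had more read pairs at E16.5 and contacts of Emx2, Sox2 and Sox1 fewer. This comparison asks whether the same contact is stronger at either stage. The contact of the Neurod2 bin with a bin inside Cdk12, 60 kb away on chromosome 11, had 78 and 67 read pairs at E12.5 and 294 and 214 at E16.5. This was a 2.71-fold increase after TMM (log2 change 1.44, SE 0.21, adjusted p = 9.2e-06). Zbtb18, a repressor gene of cortical development, contacted a bin inside Sdccag8 at 560 kb, with 17 and 23 read pairs against 106 and 64 (3.28-fold, adjusted p = 2.82e-05). The bin shared by Tbr1 and Psmd14 contacted the bin of Tank at 150 kb with 60 and 36 against 187 and 133 (2.58-fold, adjusted p = 3.49e-05). A contact of Nfib over 940 kb had 26 and 25 against 126 and 74 (3.03-fold, adjusted p = 3.39e-05), and a contact of the dopamine receptor gene Drd1 over 270 kb had 21 and 14 against 71 and 68 (3.08-fold, adjusted p = 5.04e-05). The other named increases were at Marchf10 (2.52-fold), Tmem200a (3.31-fold), Tcf4 (2.67-fold) and Lingo1 (2.47-fold), with adjusted p from 5.04e-05 to 0.000112.

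The decrease with the smallest p was at Emx2, whose contact over 690 kb with a bin at 60150001 to 60160000 on chromosome 19 had 60 and 66 read pairs at E12.5 and 22 and 28 at E16.5. It was 3.23-fold lower (log2 change -1.69, SE 0.26, adjusted p = 1.3e-05). A bin inside Pax6, the homeobox gene of radial glia, contacted the Dcdc5 bin 410 kb away with 86 and 77 against 46 and 26 (2.91-fold lower, adjusted p = 2.57e-05). Contacts of the progenitor genes Sox2 over 440 kb (80 and 90 against 48 and 34, 2.67-fold lower) and Sox1 over 160 kb (108 and 119 against 68 and 53, 2.42-fold lower) fell too, with adjusted p of 3.91e-05 and 4.56e-05. A contact of the bin of the cyclin gene Ccnd1 and LTO1 with a bin inside Tpcn2 over 280 kb fell 3.14-fold, from 44 and 42 to 17 and 18 (adjusted p = 4.97e-05). The other named decreases were at Sall1 (2.69-fold), Nr2e1 (2.17-fold), Zfp36l1 with Gm52006 (2.85-fold), Zic5 (2.86-fold) and Uncx (2.58-fold), with adjusted p from 8.48e-05 to 0.000136.

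**Figure D3:**
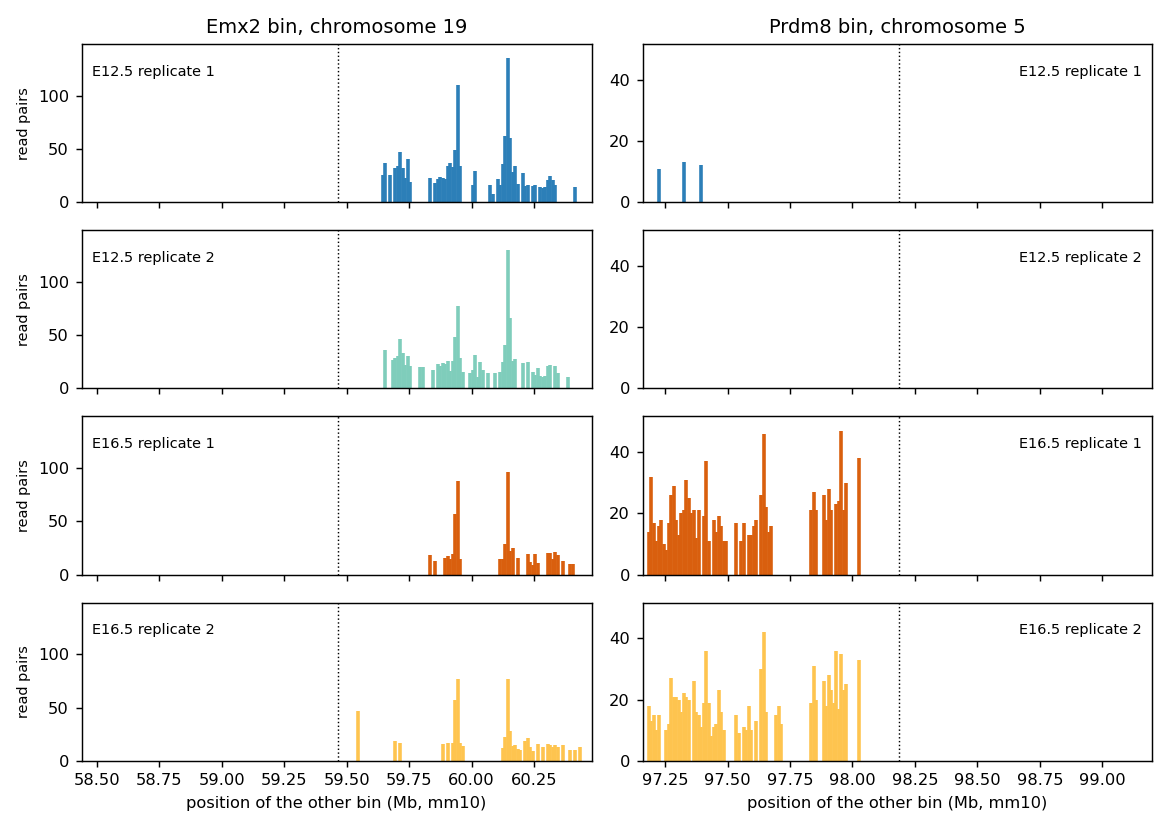
The maps show, for the Emx2 bin (left) and the Prdm8 bin (right), the position of the other bin of each listed interaction (x axis, Mb, mm10) and its read pairs (y axis) in each of the 4 libraries, with the bin itself at the dotted line. The Emx2 bin has 48 and 51 listed interactions at E12.5 and 29 and 33 at E16.5, and the Prdm8 bin has 3 and 0 against 55 and 55.

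In all, 719 of 6875 contacts passed, 404 higher and 315 lower at E16.5, and 514 of the 719 touched a gene-end bin. The called contacts that were higher had a median distance of 390 kb and those that were lower 220 kb. Most of these calls end when the authors' expected count of each contact is taken as the baseline. With it as an offset 4 contacts passed, all higher, and 690 had an unadjusted p under 0.05. The median fold of the 719 contacts went from 1.96 to 1.43, and 696 of them kept their direction. The contact of Nfib was the only named contact past the threshold with the offset (adjusted p = 0.0374). The others, named here after their values were seen, were contacts of Sox11 over 810 kb and Abcc12 over 890 kb, and a contact on chromosome 9 between the bins that start at 41590001 and 41950001, at which the table has no gene. DESeq2 called 59 higher and 39 lower. Without E12.5 replicate 1 or without E12.5 replicate 2, 149 and 132 contacts were higher and 152 and 142 lower, and 161 were lower without E16.5 replicate 2.

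Emx2, Lhx2, Tbx3 and Cd40 were the genes with the most interactions restricted to E12.5, and Prdm8, Cnr1, Plk2, Sox11 and Runx1t1 those with the most restricted to E16.5. An interaction was called restricted when both libraries of a stage listed it and neither library of the other stage did. At E12.5, the 2 end bins of Emx2 had 13 and 8 such interactions, and Lhx2 (higher-coordinate end), Tbx3 and Cd40 had 10, 10 and 9. At E16.5, Prdm8 had 45, Cnr1 31, Plk2 30, Sox11 29 and Runx1t1 29. There were 1074 interactions restricted to E12.5 and 8910 restricted to E16.5. The difference between these totals goes with list length: with lists of equal length they were 2205 and 2278.

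Listed interactions at E16.5 spanned longer distances. The median distance was 260 and 260 kb in the E12.5 libraries and 300 and 290 kb in the E16.5 libraries. The share of interactions over 200 kb was 62.1% ± 0.48 (SD, n = 2) at E12.5 and 67.7% ± 1.91 (SD, n = 2) at E16.5. Both differences were larger than the spread between replicates, with an exact permutation p of 0.333, the smallest possible. The stages did not differ beyond replicate spread in the kinds of bins that interactions join. A gene end lay in both bins in 13.2% ± 0.66 (SD, n = 2) of E12.5 interactions and 13.1% ± 0.87 (SD, n = 2) of E16.5 interactions. It lay in neither bin in 27.2% ± 2.68 and 26.8% ± 3.31 (SD, n = 2 each), and in 1 of the bins in 59.6% ± 2.02 and 60.1% ± 2.44 (SD, n = 2 each). The two-sided exact permutation p was 1 for both bins, 1 for neither and 0.667 for 1 bin.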

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

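The quasi-dispersion held at 1 or above and the whole gene span were tried only after the results were seen. Of the 20 named contacts, 20 kept their direction and side of the threshold without TMM, within distance bins, with a mean count of at least 20, with each library left out and with the quasi-dispersion of at least 1; 19 ended with the expected count as an offset and 1 with DESeq2. Of the 20 named gene-end bins, 14 passed with the quasi-dispersion of at least 1, 19 with lists of equal length and 12 with read pairs in place of interactions, while 20 ended without either E16.5 library. With clusters counted once 18 ended, and the others were not among the tested bins. No named bin or contact reversed. 

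Contacts that passed, higher and lower at E16.5, were 404 and 315. They were 59 and 39 with DESeq2, 4 and 0 with the expected count as an offset, 266 and 202 with the authors' FDR under 0.0001, 192 and 168 with 1 bin pair per cluster and 146 and 119 at distances of at most 200 kb; the last 3 tested fewer contacts (3394, 3211 and 2335). Leaving out a library gave 132 to 317 higher and 142 to 220 lower.

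Gene-end bins that passed were 181 and 53. They were 156 and 88 without TMM, 32 and 8 with DESeq2, 104 and 23 with a sum of at least 1, 56 and 25 with lists of equal length, 44 and 21 with the authors' FDR under 0.0001, 0 and 0 with clusters counted once, 69 and 25 with read pairs, 16 and 1 at most 200 kb, 20 and 4 with the quasi-dispersion of at least 1, and 443 and 141 of 4036 genes over the whole gene span. Leaving out a library gave 0 to 111 higher and 0 to 32 lower; without either E16.5 library edgeR's prior degrees of freedom fell from 7.07 to 2.52 and 4.70. The test with the start of any transcript was not run, since no transcript coordinates were at hand.

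Bins of any kind that passed were 0 and 0. They were 75 and 49 without TMM, 60 and 12 with DESeq2 and 229 and 103 with a sum of at least 20, and 0 to 404 higher and 0 to 95 lower with a library left out. Lists that passed were 3 higher and 7 lower. With read pairs the meninges list ended (adjusted p = 0.0631), and with the whole gene span the meninges and cell cycle lists (adjusted p = 0.0523 and 0.0860). The glial list passed without E12.5 replicate 1 (adjusted p = 0.0268), without E16.5 replicate 1 (0.0331) and with the replicate block (0.0429). With an estimated correlation they were 0 and 0, with fry 2 higher and 2 lower, and with lists of equal length 1 and 3 (synaptic higher; radial glia, diencephalic and non-forebrain lower). The intermediate progenitor list, not called, turned upward with fry (adjusted p = 0.677) and with lists of equal length (adjusted p = 0.583).

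Interactions restricted to E12.5 numbered 1074, against 2205 with lists of equal length, 539 with the authors' FDR under 0.0001, 396 with 1 per cluster and 1760 to 4812 with a library left out. Those restricted to E16.5 numbered 8910, against 2278, 4885, 1601 and 11182 to 22094. A library left out loosens the definition by construction. The within-stage minus between-stage Jaccard index was 0.125, and 0.168 with both ends within 1 bin, 0.0816 with lists of equal length and 0.0954 at most 200 kb. The ratio of listed interactions (1.96 to 2.24), the distance difference (30 to 40 kb) and the class shares stayed within their limits in every alternative run.

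Replicate numbers are shared between the stages but nothing says that they pair the samples. With the replicate number as a block, 532 contacts were higher and 407 lower, 308 gene-end bins were higher and 77 lower, and 466 bins of any kind were higher and 119 lower. Deviations of same-numbered libraries correlated at 0.128 over contacts and 0.0992 over gene-end bins.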

Other observations

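The use of the expected count, of distance and of the share of neurons to weigh the patterns was chosen after the results were seen, as were the genes and list values in the first 2 paragraphs. By the mean number of listed interactions over the 4 libraries, in which the longer E16.5 lists weigh more, the bin of Sox11 came first (45 and 57 at E12.5 against 92 and 92 at E16.5). At E12.5 the Sox11 bin had a lower mean than the bins of Mn1, Rnd3, Zfp703 and Jun and the bin in or near Sox6. That of Mn1 came second over the 4 libraries, with 69 and 69 against 70 and 68. A bin in or near Sox6 (63 and 69 against 68 and 73), and those of Rnd3 (52 and 61 against 67 and 78), Zfp703 (54 and 51 against 64 and 72), Enc1 (48 and 54 against 61 and 62) and Jun (54 and 55 against 55 and 54) came next. The largest cluster of neighbouring interactions in each E16.5 library lay between Mn1 and Pitpnb on chromosome 5, with 211 bin pairs in replicate 1 and 170 in replicate 2. Genes outside the fixed lists also stood among the 24 gene-end bins that passed with the quasi-dispersion of at least 1. They included Myc (9 and 10 against 48 and 64), the splicing factor gene Srrm4 (1 and 2 against 21 and 29), Hivep2 (1 and 4 against 26 and 34) and Lratd2 (2 and 2 against 19 and 34). With St3gal1, 3 more genes of glycan synthesis were there: St6galnac5 (0 and 1 against 18 and 34), B3gat2 (0 and 0 against 14 and 25) and Hs6st3 (1 and 0 against 18 and 24); their enrichment was not tested.

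Contact strength was also summarised over the lists. Contacts touching radial glia bins had fewer read pairs at E16.5, with 36 of 158 lower and 5 higher (median log2 change -0.49, adjusted p = 9.19e-14 with the preset correlation, and 0.147 with an estimated one). Diencephalic and choroid plexus bins had 16 of 56 contacts lower and 0 higher (adjusted p = 1.38e-10, and 0.147). Neurite bins had 10 of 60 higher and 0 lower, and deep-layer bins 5 of 29 higher and 0 lower (adjusted p = 0.000715 and 0.000267, and 0.147 for both with an estimated correlation). Contacts of upper-layer bins (5 of 84 higher, 1 lower, adjusted p = 0.00407, and 0.160) and of synaptic bins (5 of 14 higher, 0 lower, adjusted p = 0.0127, and 0.524) also had more read pairs. Cell cycle (adjusted p = 0.000378, and 0.156), intermediate progenitor (0.00834, and 0.156) and non-forebrain patterning bins (0.0169, and 0.674) had fewer. The 14 synaptic contacts are not the 14 bins tested for number. A contact had to be listed in all 4 libraries, so the 8 synaptic bins without a listed interaction at E12.5 gave none. The early timing list, lower in number, had a median of 0.15 and did not pass (adjusted p = 0.903), nor did the GABAergic (0.459), glial (0.584) and meninges lists (0.0552). With the authors' expected count as an offset, the deep-layer list (adjusted p = 0.00653) and the diencephalic list (adjusted p = 0.00331) were the only lists that passed with the preset correlation, and 0.283 was the value of both with an estimated one.

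The first pattern weighed is the 719 contacts that differ in read pairs between stages. A different decay of contacts with distance was argued against, since 329 of the 404 higher and 285 of the 315 lower contacts still passed after normalizing within distance bins, which gave 674 calls in all. Called contacts of the same bin mostly moved together: of 405 pairs of called contacts that share a bin and reach bins over 100 kb apart, 98.3% moved the same way. A bin with many called contacts enters many pairs, so the pairs are not independent, and contacts that were not called do not enter. Once the authors' expected count was the baseline, 4 contacts passed. Both results go with a change in the coverage of the bins, which may include their H3K4me3 level. The content of the expected count is not stated. Change of single contacts beyond that baseline stays open, since 10.0% of contacts had an unadjusted p under 0.05 with the offset, while 4 passed after adjustment.

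The second pattern is the lower relative number of listed interactions at radial glia, non-forebrain patterning and diencephalic genes at E16.5, lists that do not pass with an estimated correlation (adjusted p = 0.274, 0.365 and 0.300). Well-connected bins could reach a ceiling while the E16.5 lists grow, so each list was set against 10000 random lists of bins matched on the sum over the 4 libraries. The radial glia median lay at percentile 0.02 (2 random lists as low), and the non-forebrain and diencephalic medians at percentile 0 (0 as low), with matched medians of 0.10, 0.15 and 0.10 on the log2 scale against -0.72, -0.93 and -1.02. These random lists treat bins as independent. The estimated correlation was 0.604 for the non-forebrain list, 0.370 for the diencephalic list and -0.0015 for the radial glia list. The 3 lists were taken up for their low values in these data, and the longer E16.5 lists weigh more in the matched sum. The percentiles alone therefore do not decide on a ceiling. With lists of equal length from the same libraries, which removes the longer E16.5 lists, fewer bins reached the minimum sum. The medians were then -0.85 (radial glia, 18 bins), -1.04 (non-forebrain, 26 bins) and -1.14 (diencephalic, 13 bins). These values argue against a ceiling that acts through list length as the whole account of the 3 medians. The development of the tissue between the stages, and a difference in dissection or cell makeup, stay open as untested.

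The third pattern is that 8 of 14 synaptic bins had no listed interaction at E12.5. Among 10000 random lists matched on the E16.5 sum, a median of 1 bin was at 0. No random list reached 8, which puts the synaptic list at percentile 100. The synaptic list was taken up for its values in these data, and the random lists treat bins as independent. The percentile alone therefore does not decide on shorter E12.5 lists. With lists of equal length, 5 synaptic bins were tested, and the list stayed higher (camera adjusted p = 0.000366 with the preset correlation). With the full lists and an estimated correlation it did not pass (adjusted p = 0.274). A higher share of neurons at E16.5 may account for the 8 bins at 0. With these libraries it cannot be told apart from change within neurons, whatever the lists show. The test set for it asked whether the neurite, deep-layer and upper-layer lists were all higher. The upper-layer list did not pass in number (adjusted p = 0.361), though it did in contact strength (0.00407). The neurite and deep-layer lists, higher in number, did not pass with an estimated correlation (0.300 for both) or with lists of equal length (0.227 and 0.132). That test was first written with the GABAergic list and was rewritten after the values were seen; the GABAergic list, which also holds progenitor genes, had a median log2 change of -0.39, but its call did not hold (adjusted p = 0.464 with an estimated correlation, 0.108 with lists of equal length and 0.186 without E16.5 replicate 2), so it does not settle the question. No sample analysed here measures the share of neurons.

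A split by replicate number appeared in the kinds of bins joined. A gene end lay in neither bin in 29.1% and 29.2% of interactions in replicate 1 of E12.5 and E16.5, and in 25.3% and 24.5% in replicate 2. The stages did not show this split.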
